A study of Mus musculus with 6 samples.

How the data were processed

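Per the labels' protocols, wild-type and RBPjcKO mice were injected with tamoxifen, liver sinusoidal endothelial cells were isolated, total RNA was extracted with Trizol, and Illumina libraries were sequenced as paired reads on a HiSeq 3000. How the cells were purified is not given in the sources used here. Libraries were grouped by the genotype label into 3 wild-type and 3 RBPjcKO libraries, and no batch, litter or pairing is labelled. Replicate numbers follow the order of the samples and pair nothing.

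Per the submitters' processing notes, reads were converted with bcl2fastq and aligned with TopHat2 2.0.13 to the mouse genome (mm10, GRCm38). The tool that counted reads, its annotation and its strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be assigned with certainty. Per the file headers, the deposited table holds a raw read count per gene and library, made by the authors without normalisation. The authors also deposited RPKM values, in which each count is divided by gene length and by the total of its own column, and the ratio of the implied total to the column total was 1.0 in each library. Even numbers made up 54.4% to 56.0% of counts between 1 and 19, a pattern that counting both mates of a pair would leave, which was not tested further. Gene starts equalled the RefSeq start on GRCm38, counted from 1, for 12920 of 22775 genes compared.

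The table had 56825 entries, of which 33353 were FANTOM3 cDNA clones and 23472 named genes, and 1 entry was emptied for this work. Clones were left out because reads over a gene are counted again in clones that overlap it, a choice made after the names in the table were seen. Spreadsheet dates stood in place of 27 gene names and were resolved by Entrez identifier. The counts over named genes ran from 30958761 to 40459702 per library, and over all entries from 37307663 to 48370102. Clones took 15.95% to 17.36% of counts, the ribosomal precursor Rn45s 0.60% to 1.43% of those in named genes, and the 10 most abundant genes 6.19% to 7.28%. Transcripts encoded by mitochondrial DNA were not analysed here.

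The tests, thresholds, the gene lists of the report, rule for named genes and first set of alternatives were chosen before the data were examined. Counts were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.204. The standard error of a log2 fold change was taken as its size over the square root of F, an approximation. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, which can be too lenient where the genes of a list vary together between libraries. A camera fit with an estimated correlation is therefore given beside each called list, and fry was a further alternative. List p-values were adjusted over the 33 lists, and genes were also adjusted over the list alone. The mesothelial list and others are short, with 6 genes at the fewest. Tables and figures were prepared with Python 3.11.15.

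The genes named are Rbpj and the Notch lists where a group reached 1 CPM, the 10 largest rises and 10 largest falls among called genes with at least 1 CPM in a group (predicted genes and antigen receptor genes left out), up to 3 called genes with no count in a group, and up to 4 called members of each other list by size of change, or the 2 most abundant where none was called. Values of some genes that the rule names are not reported here. Genes named outside this rule were chosen after their values were seen: Obsl1, Plau, Ltbp4, Stab2, Lyve1, Gata4, Wnt2, Wnt9b, Nos3, Mki67, Mcm3, Mcm5, Pcna, Icam2 and Pfkfb3, with those of the loci and channel genes among the other observations. For genes with no count in a group the fold sets the mean of the other group against a floor of 3 counts over the group without counts. If both mates of a pair were counted, that floor stands for fewer read pairs.

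The alternatives chosen in advance were DESeq2 1.42.0 with its size factors, no filter, a count of at least 5 in at least 3 libraries, leaving out each library, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and the 2 other list tests. Alternatives added after the data were seen were CPM of at least 5 in 3 libraries, clones included, upper-quartile scaling, no scaling beyond library totals, the robust quasi-likelihood fit, the mean log2 level of 34 hepatocyte markers per library as a covariate, and limma on log2(RPKM + 1). Those meant for a table of normalised values or of the authors' test results were not needed for a table of counts.

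The analysis was tested on simulated counts of 14869 genes, 200 of them changed, at the depth of these libraries and their trend of dispersion with expression. It recovered 31.3% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 90.9% of those changed 4-fold, and 9 of 138 calls (6.5%) were unchanged genes. Changes of each of these sizes can therefore be missed at 3 libraries per group, the smaller ones more often. Simulated genes did not vary in dispersion around the trend, and fewer were changed than the 2489 called in the data. The rates for these libraries may therefore differ. In a separate simulation without these changes, camera called a list raised 1.5-fold and did not call an unchanged list. Genes were drawn independently there, so camera was not tested on lists whose genes vary together.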

Results

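Transcript levels in liver sinusoidal endothelial cells (LSECs), the fenestrated cells that line the hepatic sinusoids, were measured by RNA sequencing in wild-type C57BL/6 mice and in mice with a tamoxifen-induced conditional knockout of Rbpj in endothelium (RBPjcKO). Rbpj encodes the DNA-binding protein through which Notch receptors act on transcription. Each group held 3 libraries, and the named genes of the deposited table received between 30958761 and 40459702 counts per library. After the filter on low counts 14869 genes were compared. Across genes, Pearson's r of log2 CPM (counts scaled to library size) was 0.979 to 0.985 between libraries of the same group and 0.944 to 0.967 between groups, as a description, since genes are not independent replicates. The first principal component held 55.3% of the variance and separated the groups. Levels are given as mean ± SD of TMM-normalised CPM over the 3 libraries of a group, and the error of a log2 fold change is its standard error (SE). The labels do not state that each library came from a separate animal, so the p-values measure the spread between these libraries.

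The first question was whether the targeted gene and its pathway were lower in the knockout libraries. Rbpj (chromosome 5, 53555779 to 53657445, GRCm38) fell from 44.7 ± 2.76 CPM in wild-type to 18.1 ± 1.49 CPM in RBPjcKO cells (n = 3 each), a 2.47-fold reduction, with 1439 to 1753 counts in the wild-type and 655 to 795 in the RBPjcKO libraries. The log2 fold change was -1.30 (SE 0.10), with adjusted p = 0.000982 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. These are counts over the whole gene, so reads from outside the deleted part are included. Hes1, a transcriptional repressor and direct Notch target, fell 2.49-fold from 189 ± 16.1 to 75.9 ± 10.4 CPM (adjusted p = 0.00164 by edgeR's quasi-likelihood test). Efnb2, which encodes the arterial ligand ephrin-B2, fell 2.40-fold from 156 ± 4.67 to 65.0 ± 11.1 CPM, and Jag1, a Notch ligand, fell 3.26-fold from 42.0 ± 3.10 to 12.9 ± 2.76 CPM.

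Of 37 measured Notch pathway and target genes, 13 changed, 8 of them lower and 5 higher in RBPjcKO. Among the 17 target genes, Gja5 and Gja4, which encode the arterial gap junction proteins connexin 40 and connexin 37, fell 10.6-fold and 2.07-fold, Notch3 fell 2.13-fold and Sox17 fell 1.27-fold. The log2 fold change of Gja5 was -3.403, and ran from -4.245 to -2.969 when a library was left out. Myc, listed as a Notch target from other cell types, rose 10.5-fold, from 33.7 ± 8.30 to 353 ± 38.5 CPM (log2 fold change 3.39, SE 0.20, adjusted p = 0.000405 by edgeR's quasi-likelihood test). Other canonical targets did not pass the test. Hey1 stood at 6.43 ± 1.68 and 5.05 ± 2.65 CPM, Heyl at 10.2 ± 2.23 and 10.2 ± 0.909, Nrarp at 70.0 ± 13 and 79.2 ± 22.0, and Dll4 at 367 ± 49.6 and 321 ± 35.6, in wild-type and RBPjcKO cells. Among the 22 pathway components, Notch4, Dll1, Maml3 and Mfng rose by 1.41-fold, 1.54-fold, 1.57-fold and 1.40-fold, while Notch1 (log2 fold change 0.08, SE 0.12) and Notch2 (-0.25, SE 0.12) were not called. Adjusted over the list alone, 2 target genes were higher and 6 lower, and 4 components were higher and 3 lower. As sets, the targets had a median log2 fold change of -0.34 (-0.21 without RBPjcKO replicate 1; adjusted p = 0.0845 by limma's camera), the components had adjusted p = 0.814, and with an estimated correlation adjusted p = 0.50 and 0.93. By fry, the further alternative, the targets were lower (adjusted p = 0.0334) and the components were not called (adjusted p = 0.796). The number of called Notch genes dropped to 7 without wild-type replicate 2 and to 7 without wild-type replicate 3, and Notch3, Notch4, Dll1, Mfng, Gja4 and Sox17 lost their call in at least 1 of the fits without a library. Rbpj, Hes1, Efnb2, Jag1, Gja5, Maml3 and Myc kept an adjusted p under 0.05 in each of the 6 fits that left out 1 library.

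**Figure D1:**
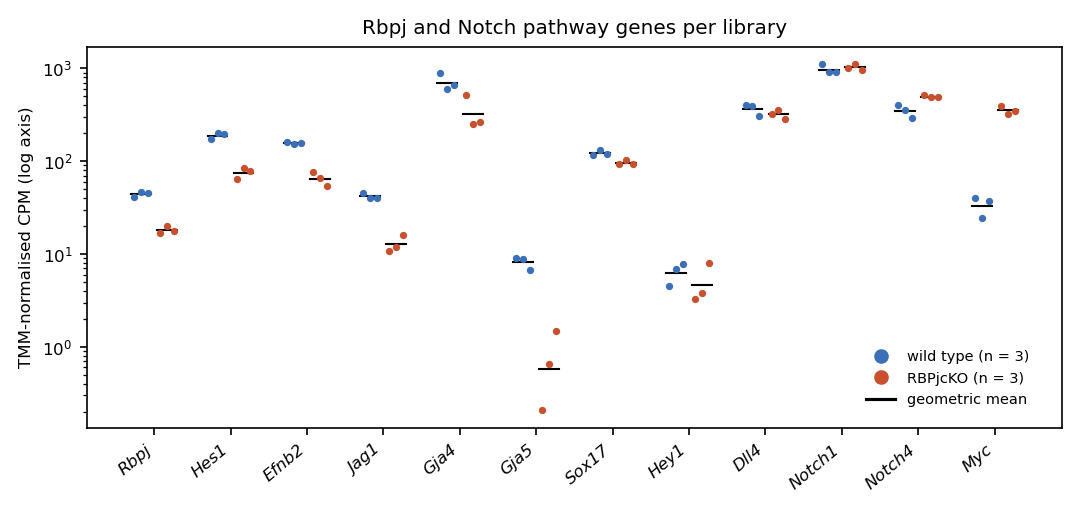
Each point is 1 library, plotted as TMM-normalised CPM on a log axis, for Rbpj and 11 other Notch pathway genes, with wild-type libraries in blue, RBPjcKO libraries in red (n = 3 each) and a bar at the geometric mean. Rbpj fell from 44.7 to 18.1 CPM and Myc rose from 33.7 to 353 CPM, while Hey1, Dll4 and Notch1 were not called.

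Across all genes, 2489 of 14869 (16.7%) differed between the groups at an adjusted p under 0.05, of which 1338 were higher and 1151 lower in RBPjcKO (edgeR's quasi-likelihood test). A change of at least 1 on the log2 scale was seen for 895 of them, 465 higher and 430 lower. The 3 libraries of one group lay wholly above those of the other for 5995 genes (40.3%), where chance alone gives 10%. The gene with the lowest p, chosen after its values were seen, was Obsl1, which encodes a cytoskeletal linker and rose 23.9-fold from 17.7 ± 2.80 to 424 ± 5.12 CPM. The count depended on the libraries. It was 796 (467 higher, 329 lower) without wild-type replicate 2, 1549 (869 higher, 680 lower) without wild-type replicate 3 and 1433 (846 higher, 587 lower) without RBPjcKO replicate 2. Without wild-type replicate 1 or RBPjcKO replicate 1 the genes called lower numbered 767 and 676, and without RBPjcKO replicate 3 those called higher numbered 876. Of 110 named genes called here, 64 kept an adjusted p under 0.05 in each of the 6 fits without a library.

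**Figure D2:**
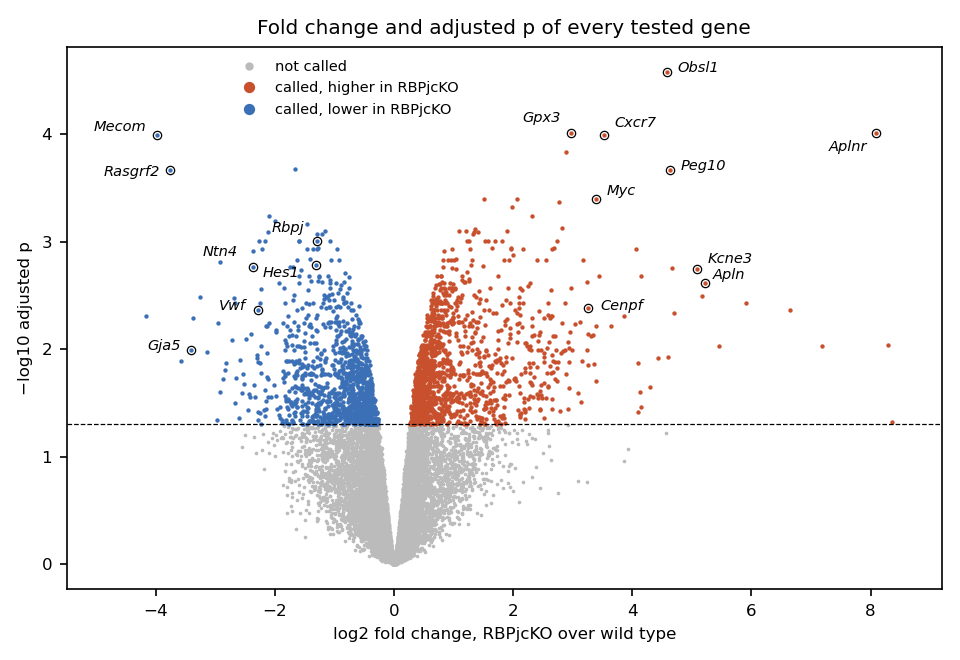
Each point is 1 of 14869 genes, with the log2 fold change of RBPjcKO over wild type on the horizontal axis and −log10 of the adjusted p on the vertical axis. The dashed line marks an adjusted p of 0.05. The 1338 genes called higher (red) reach a log2 fold change of 8.09 at Aplnr among the labelled genes, and the 1151 called lower (blue) reach -3.98 at Mecom among the labelled genes.

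Among the 10 largest rises, wild-type levels ran from near absence to 6.64 CPM at Peg10. Aplnr, the apelin receptor, stood at 0.132 ± 0.0261 CPM in wild-type and 36.9 ± 10.6 CPM in RBPjcKO cells, a 272-fold rise (log2 fold change 8.09, SE 0.32), and its ligand gene Apln rose 37.2-fold from 0.640 ± 0.252 to 24.0 ± 14.9 CPM. The potassium channel genes among them were Kcnh1, which rose 60.2-fold, and Kcne3, which rose 34.1-fold (1.75 ± 1.24 to 59.9 ± 18.0 CPM). The log2 fold change of Kcne3 was 5.091, and ran from 4.715 to 5.843 when a library was left out. Kcnc2, of the same class, had no count in wild-type libraries and 25 to 63 counts in the RBPjcKO libraries. Its RBPjcKO mean stood 37-fold above a floor of 3 counts over the wild-type group. Meox2, an endothelial homeobox gene, likewise had no wild-type count and 12 to 104 RBPjcKO counts, with a mean 38.8-fold above that floor. Its levels were 0.337, 0.299 and 2.67 CPM in the RBPjcKO libraries, so that mean rests mostly on replicate 3. The adjusted p of Meox2 reached 0.11 when a library was left out. The other large rises were Peg10, an imprinted gene (24.9-fold, 6.64 ± 1.48 to 166 ± 41.0 CPM), Sox11 (25.4-fold), Prdm8 (35.9-fold), Csmd1 (26.1-fold), the granulocyte gene Mpo (43.9-fold) and Fgf23, a hormone gene (24.3-fold). Mpo and Fgf23 varied between the knockout libraries, at 5.53 ± 5.23 and 7.67 ± 7.63 CPM, and the adjusted p of Fgf23 reached 0.056 when a library was left out.

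The deepest falls included Mecom, which encodes a transcription factor of arterial endothelium and blood stem cells (15.8-fold, 26.0 ± 3.03 to 1.64 ± 0.244 CPM), and Rasgrf2, a Ras exchange factor gene (13.6-fold, 26.0 ± 5.58 to 1.91 ± 0.151 CPM). Ism1, which encodes the secreted protein isthmin-1, fell 17.9-fold to 0.0676 ± 0.0277 CPM, near the detection limit. Myrip fell 11.9-fold, Gpr126 (now Adgrg6), an adhesion receptor gene, fell 9.57-fold from 21.4 ± 4.32 to 2.24 ± 1.24 CPM, and Fam107a fell 8.80-fold. The basement membrane gene Col4a3 fell 7.78-fold, the pseudogene Olfr1372-ps1 fell 10.4-fold, and Prrt4 fell 7.88-fold, with an adjusted p of up to 0.12 when a library was left out. The log2 fold changes of Myrip, Olfr1372-ps1 and Prrt4 were -3.573, -3.375 and -2.979. They reached -4.466, -4.09 and -4.212 when a library was left out.

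Vascular zones were compared next, because LSECs differ between the portal and central ends of the sinusoid. Genes of periportal endothelium fell as a group. Of 14 measured, 9 fell and the other 5 did not pass the test, with a median log2 fold change of -1.37. Besides Mecom, Gja5 and Gpr126, Ntn4, which encodes netrin-4, fell 5.19-fold (296 ± 23.9 to 57.0 ± 17.1 CPM), Ltbp4 fell from 2361 ± 109 to 523 ± 112 CPM and Msr1, a scavenger receptor gene that macrophages also express, fell 3.44-fold. Adjusted over the list alone, 9 were lower and 1 higher. The list was lower by camera (adjusted p = 1.42e-17) and was the only one of 33 lists to keep its call with an estimated correlation (adjusted p = 0.0233). Cholangiocyte markers, which also belong to the portal tract, moved the same way, with a sum of 388 ± 139 CPM in wild-type and 166 ± 41.7 CPM in RBPjcKO libraries. Of 15 arterial genes 7 fell, among them Gja5, Vegfc (3.29-fold), Jag1 and Efnb2, with a median of -0.50 (-0.33 without RBPjcKO replicate 1, -0.87 without RBPjcKO replicate 3 and -1.05 with 4 lower under the hepatocyte covariate; 8 lower and 1 higher adjusted over the list alone). At least Gja5, Jag1 and Efnb2 are also in the Notch lists, and Gja5 is in the periportal list, so the falls of these lists are not independent. The arterial list was lower by camera (adjusted p = 6.87e-05), and adjusted p = 0.41 with an estimated correlation. By fry it was called lower (adjusted p = 0.0229). Its calls were 4 lower without wild-type replicate 2, and 1 higher appeared without wild-type replicate 1 or RBPjcKO replicate 1, while the periportal calls moved by less than 1.5 times in each fit.

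Pericentral and venous genes moved both ways. Of 14 pericentral genes 3 rose and 3 fell (4 and 4 adjusted over the list alone). Rab3b, a vesicle traffic gene, rose 4.48-fold, while Dkk3, which encodes a secreted protein of the Dickkopf family, fell 5.59-fold (192 ± 12.5 to 34.3 ± 20.8 CPM), Cdh13 fell 4.30-fold and Rspo3, which encodes a secreted amplifier of Wnt signalling, fell 3.83-fold (49.8 ± 12.4 to 13 ± 2.2 CPM). The Wnt ligand genes Wnt2 (223 and 283 CPM in wild-type and RBPjcKO) and Wnt9b (81.2 and 59.4 CPM) were not called. Of 9 venous genes 2 rose, Aplnr and Flt4, and 3 fell, including Vwf, which encodes von Willebrand factor (4.88-fold, 584 ± 189 to 120 ± 30.2 CPM), and Cpe (3.41-fold), and 3 and 3 passed when adjusted over the list alone. Neither set passed camera (adjusted p = 0.713 for pericentral and 0.239 for venous). By fry the venous list was called higher (adjusted p = 0.0334) and the pericentral list was not called (adjusted p = 0.597). Of the venous genes 4 had a log2 fold change above 0 and 5 below, at a median of -0.01. Their mean of 0.65 leans on Aplnr, at 8.09, and fry was not run without it. Of 22 angiocrine factor genes, which encode signals from endothelium to hepatocytes, 6 fell and 3 rose (9 and 3 adjusted over the list alone). Bmp4 fell 2.61-fold, Pdgfb 1.81-fold and Cxcl12 1.80-fold, from 594 ± 27.7 to 330 ± 115 CPM. This list had a median of -0.43 and was called by camera (adjusted p = 0.0284), and adjusted p = 0.50 with an estimated correlation. By fry it was called lower (adjusted p = 0.0408). Stellate cell and fibroblast markers, which share 5 members with the angiocrine and extracellular matrix lists, had a median of -0.28 in the same comparison. Without wild-type replicate 2 the calls were 1 higher and 2 lower for angiocrine, 1 higher for pericentral and 1 and 1 for venous genes. The venous calls were also 1 and 1 without wild-type replicate 3 or RBPjcKO replicate 1, and 1 lower without RBPjcKO replicate 2.

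LSEC identity genes moved both ways. Of 25, 6 fell and 3 rose, 6 and 5 adjusted over the list alone and 7 and 6 by DESeq2 (camera adjusted p = 0.295). Ehd3, an endocytic recycling gene and an abundant LSEC transcript, fell 2.10-fold from 6023 ± 721 to 2871 ± 220 CPM, Clec4g, a C-type lectin gene, fell 1.85-fold and Dnase1l3 fell 1.80-fold, whereas the fatty acid transporter gene Cd36 rose 1.81-fold from 297 ± 24.5 to 538 ± 78.8 CPM. Stab2 (3989 ± 286 and 4964 ± 418 CPM), Lyve1 (528 and 674 CPM) and Gata4 (763 and 736 CPM) were not called. Of 21 scavenger and endocytosis genes 4 fell, including Scarb2 (1.93-fold), and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.305). Of 20 genes of continuous capillary endothelium 7 rose, among them Apln and Esm1 (2.60-fold), and 4 fell, among them Vwf (8 and 5 adjusted over the list alone, camera adjusted p = 0.509). Of 17 fatty acid transport genes 6 rose, including Fabp4 (2.23-fold) and Lipg (2.08-fold), as did Apold1 of this list (2.46-fold), and 2 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.221). The identity calls were 1 higher and 3 lower without wild-type replicate 2 or 3 and 1 higher and 4 lower without RBPjcKO replicate 2. Without wild-type replicate 2 the calls were 1 higher for scavenger, 4 higher for capillary and 2 higher with 0 lower for fatty acid genes. Without wild-type replicate 1, wild-type replicate 3 or RBPjcKO replicate 1 the fatty acid calls were 3 higher and 1 lower, and without RBPjcKO replicate 2 they were 4 higher and 0 lower. With the hepatocyte covariate the calls were 1 higher and 0 lower for fatty acid genes, 3 and 3 for capillary genes and 1 and 1 for identity genes.

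Genes of sprouting endothelium moved both ways. Of 24 tip cell and angiogenesis genes 10 rose and 4 fell (12 and 7 adjusted over the list alone), with a median log2 fold change of 0.33. Besides Aplnr and Apln, Plaur, the urokinase receptor gene, rose 4.86-fold (21.1 ± 5.94 to 103 ± 24.2 CPM) and Nid2, a basement membrane gene, rose 4.18-fold, with the caution that Nid2 shares its span with 2700060E02Rik on the other strand. Plau, the urokinase gene, lies outside the lists and rose from 45.9 to 341 CPM. The tip cell list was called by camera (adjusted p = 0.000678), and adjusted p = 0.50 with an estimated correlation. By fry it was called higher (adjusted p = 0.0408). Its calls were 7 higher and 1 lower without wild-type replicate 2, and 2 lower without RBPjcKO replicate 1. With the hepatocyte covariate they were 3 higher and 2 lower at a median of 0.13, and the summed level was 13920 ± 1423 and 14250 ± 925 CPM in wild-type and RBPjcKO libraries. Of 30 extracellular matrix genes 9 rose and 6 fell, and equally many passed when adjusted over the list alone. The collagen IV gene Col4a2 rose 2.17-fold (882 ± 47.5 to 1915 ± 278 CPM) and Col15a1 2.43-fold, and Timp3, a metalloproteinase inhibitor gene, fell 2.48-fold from 1644 ± 91.5 to 664 ± 187 CPM (camera adjusted p = 0.0766 for the list). Of 20 genes of nitric oxide and cyclic GMP signalling 4 rose and 2 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.864). Nos2 rose 5.97-fold from a low level, 1.09 ± 0.447 CPM, Ddah2 rose 1.84-fold, Ddah1 fell 3.05-fold and Pde5a fell 1.68-fold, while Nos3 was not called at 269 and 296 CPM. With the hepatocyte covariate the matrix calls were 3 higher and 2 lower, and without RBPjcKO replicate 3 they were 7 and 7. Matrix genes called lower numbered 3 without wild-type replicate 1, 2 or 3 or RBPjcKO replicate 1 or 2. Nitric oxide calls were 2 higher and 1 lower without wild-type replicate 2, 1 lower without wild-type replicate 3 or RBPjcKO replicate 2, and 5 lower without RBPjcKO replicate 3.

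Of 30 cell cycle genes 21 rose in RBPjcKO and the other 9 did not pass the test, and 23 rose when adjusted over the list alone. The median log2 fold change was 2.24. Cenpf, a kinetochore gene, rose 9.57-fold (1.84 ± 0.536 to 17.6 ± 7.97 CPM), Bub1, a spindle checkpoint gene, 7.95-fold, Nusap1 7.04-fold and Kif11, a mitotic kinesin gene, 6.68-fold. The log2 fold changes of Bub1 and Kif11, 2.99 and 2.741, reached 3.652 and 3.445 when a library was left out. The adjusted p of Kif11 then reached 0.065. Mki67 rose from 14.4 to 69.3 CPM. Among the 9 not called were Mcm3 (79.9 and 74.4 CPM) and Pcna (114 and 118 CPM), while the replication gene Mcm5 rose from 19.2 to 36.9 CPM. The list was called by camera (adjusted p = 3.90e-17), and adjusted p = 0.50 with an estimated correlation. By fry it was called higher (adjusted p = 0.0408). Hepatocyte markers, whose sums overlapped between the groups, had a median of 1.16 in this comparison (0.56 without RBPjcKO replicate 3), and with their level per library as a covariate 2 cell cycle members were called, at a median of 2.00. Of 15 senescence genes 4 rose, namely Lmnb1 (3.46-fold), which encodes lamin B1 and is known to decline in senescent cells, Cdkn2a (3.44-fold) and Cdkn2b (2.66-fold), which encode cyclin kinase inhibitors, and Trp53 (1.89-fold). Adjusted over the list alone 5 rose (camera adjusted p = 0.00499), and adjusted p = 0.51 with an estimated correlation. The rise of Lmnb1 counts toward this camera result, although it is opposite to the decline known in senescent cells. Without wild-type replicate 2 the senescence calls were 2, without RBPjcKO replicate 3 there was 1 lower, and with the hepatocyte covariate there were 1 higher and 1 lower.

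Of 32 ribosomal protein genes 25 rose (28 adjusted over the list alone), with a median log2 fold change of 0.56. Rplp0 rose 2.14-fold (479 ± 64.6 to 1027 ± 227 CPM), Rps2 2.02-fold, Rpl32 1.88-fold and Rps19 1.76-fold. The summed level was 11360 ± 495 CPM in wild-type and 16630 ± 444 CPM in RBPjcKO libraries. Camera called the list (adjusted p = 1.66e-18), and adjusted p = 0.25 with an estimated correlation. By fry it was called higher (adjusted p = 0.0013). The calls were 16 without wild-type replicate 2 and 7 with the hepatocyte covariate, at a median of 0.49. Reads of ribosomal protein genes can be shared with processed pseudogenes. Of 21 glycolysis and hypoxia genes 9 rose and 1 fell (16 and 1 adjusted over the list alone). Slc16a3, a lactate transporter gene, rose 3.62-fold, the glucose transporter gene Slc2a1 2.71-fold (18.6 ± 3.39 to 50.3 ± 20.7 CPM), Pkm 1.97-fold and Pfkl 1.88-fold. Camera called this list as well (adjusted p = 1.12e-05), and adjusted p = 0.51 with an estimated correlation. Its calls were 2 without wild-type replicate 2, 4 higher and 1 lower without wild-type replicate 3, and 1 higher and 1 lower with the hepatocyte covariate. The gene called lower, Pfkfb3, lost its call without wild-type replicate 1 or 2 or RBPjcKO replicate 1 or 2.

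Of 23 inflammation genes 5 rose (9 and 1 lower adjusted over the list alone), namely Sele, which encodes E-selectin (6.85-fold, 19.8 ± 2.43 to 136 ± 27.4 CPM), Icam2 and the chemokine genes Cxcl9 (4.78-fold), Cxcl2 (2.65-fold) and Cxcl1 (1.77-fold). Camera called the list (adjusted p = 0.000493), and adjusted p = 0.51 with an estimated correlation. Its calls were 2 without wild-type replicate 2, and 1 and 2 members were called lower without RBPjcKO replicate 2 and 3. With the hepatocyte covariate its calls were 2 and its median 0.16 against 0.67, which was 0.42 without RBPjcKO replicate 3. Neutrophil markers, which can accompany such chemokines, had a median log2 fold change of 1.42 in the same comparison. Of 19 antigen presentation genes 2 fell, B2m (1.52-fold) and Cd274 (1.78-fold), and 1 was lower adjusted over the list alone. The list had a median of -0.57 (-0.36 without wild-type replicate 1, camera adjusted p = 0.00332), and adjusted p = 0.53 with an estimated correlation. Macrophage markers, from cells rich in such transcripts, had a median of -0.66 (-1.08 without RBPjcKO replicate 1 and -0.35 without RBPjcKO replicate 2) and a sum of 3251 ± 978 and 1888 ± 817 CPM in wild-type and RBPjcKO libraries. Of 22 interferon response genes Rsad2 (1.73-fold) and Ifi44 (1.68-fold) rose and Gbp2 fell 1.48-fold, with the same counts adjusted over the list alone (camera adjusted p = 0.221). Of 23 immediate early and heat shock genes, which respond to tissue dissociation, 0 were called by edgeR, with 3 at an unadjusted p under 0.05 and 3 called by DESeq2. Jun stood at 6704 ± 1800 and 6149 ± 620 CPM in wild-type and RBPjcKO cells (camera adjusted p = 0.967), and 1 member was called lower without wild-type replicate 2 or RBPjcKO replicate 3. Antigen presentation calls were 1 lower without wild-type replicate 1, 2 or 3 or RBPjcKO replicate 1. Interferon calls were 0 without wild-type replicate 2, 5 higher without wild-type replicate 1, 1 higher without wild-type replicate 3 or RBPjcKO replicate 1 or 3, and 0 lower without wild-type replicate 3 or RBPjcKO replicate 1 or 2. For the Notch component, pericentral, venous, nitric oxide and dissociation lists the median and the direction of camera differed in sign.

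**Figure D3:**
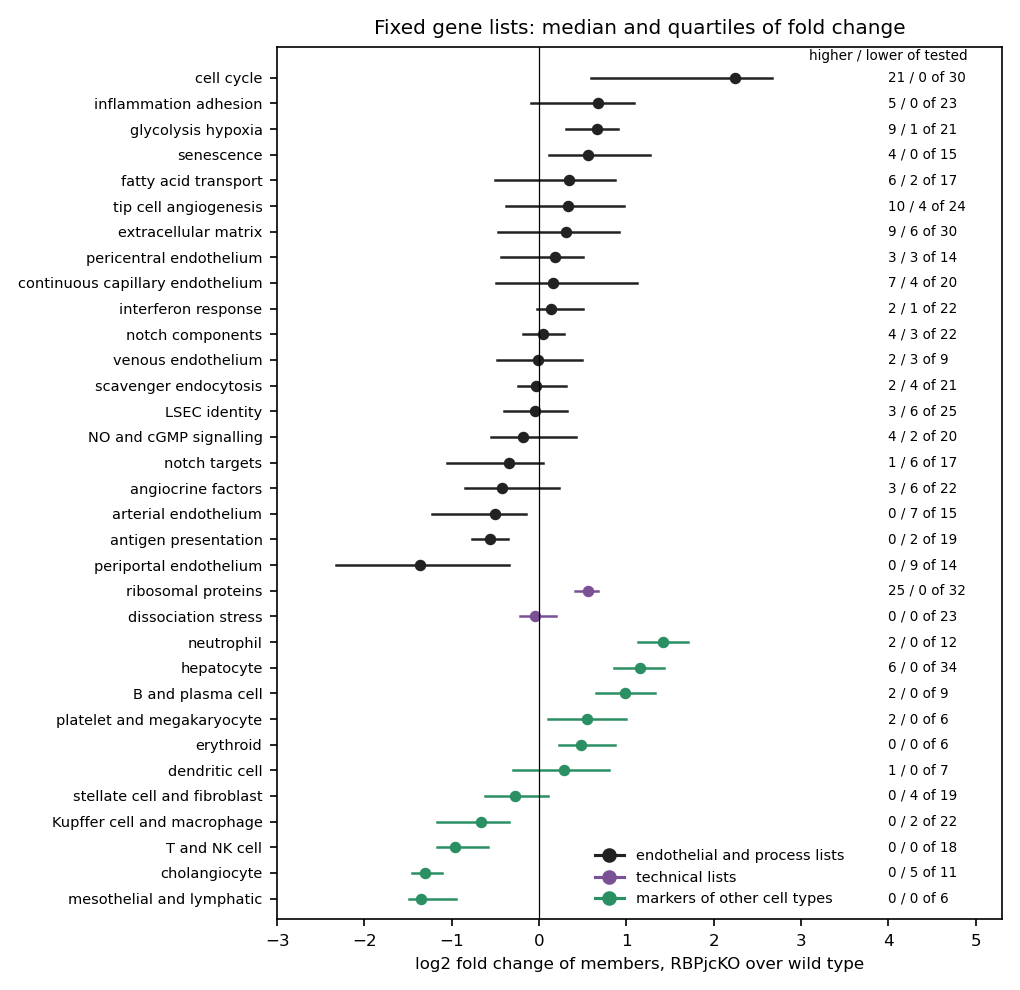
Points are the median log2 fold change of RBPjcKO over wild type for each of 33 gene lists and lines its quartiles, with the number of members called higher and lower of those tested at the right. Periportal endothelium has a median of -1.37 with 9 of 14 genes lower, cell cycle 2.24 with 21 of 30 higher, and ribosomal proteins 0.56 with 25 of 32 higher.

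Markers of other liver cells were examined because an endothelial fraction can hold them. Of 34 hepatocyte markers 6 rose and 28 did not pass the test (12 rose adjusted over the list alone), including the fibrinogen genes Fgb (3.04-fold), Fga (2.65-fold) and Fgg (2.61-fold) and the apolipoprotein gene Apoa1 (2.70-fold), with a median log2 fold change of 1.16. Their sum was 3429, 1879 and 2324 CPM in the wild-type and 2855, 3762 and 7531 CPM in the RBPjcKO libraries. The calls were 0 without wild-type replicate 2 or 3, 12 without RBPjcKO replicate 1, and 4 with a median of 0.56 without RBPjcKO replicate 3. Cholangiocyte markers were lower, with 5 of 11 called, among them Spp1, Epcam and Cldn7 (2.76-fold, 2.75-fold and 2.47-fold), and 11 lower adjusted over the list alone. Their calls were 1 without wild-type replicate 2, 2 without wild-type replicate 1, and 0 without RBPjcKO replicate 1 or 2. Of 22 Kupffer cell and macrophage markers Slc40a1 (2.46-fold) and Aif1 (2.38-fold) fell, with 2 lower adjusted over the list alone. Of 19 stellate cell and fibroblast markers 4 fell, Reln (2.08-fold, 636 ± 94.5 to 305 ± 101 CPM), Hand2 (1.89-fold), Pdgfra (1.54-fold) and Dcn (1.53-fold), and 5 adjusted over the list alone. Stellate calls were 2 lower without wild-type replicate 1 or 2 or RBPjcKO replicate 2 and 7 without RBPjcKO replicate 3, and macrophage calls were 4 without RBPjcKO replicate 1 and 1 without wild-type replicate 1 or 3 or RBPjcKO replicate 2 or 3. The stellate list shares 5 members with the matrix and angiocrine lists.

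Of 12 neutrophil markers Mpo and Elane rose (2 adjusted over the list alone), and the sum of all 12 was 377 ± 292 CPM in wild-type and 945 ± 414 CPM in RBPjcKO libraries. The B cell genes Ms4a1 and Cd79a rose 4.55-fold and 2.50-fold, to 0.985 ± 0.144 and 4.93 ± 1.31 CPM, out of 9 measured, with 5 higher adjusted over the list alone. Ppbp and Itga2b rose among 6 platelet markers and Ccr7 (2.34-fold) among 7 dendritic cell markers, with 2 and 1 adjusted over the list alone. Of 18 T and NK cell markers 0 were called by edgeR (2 at an unadjusted p under 0.05, 2 by DESeq2), of 6 mesothelial and lymphatic markers 0 (3 and 3), and of 6 erythroid markers 0 (0 and 0), and none of these passed when adjusted over the list alone. Without a library the T and NK calls were 10 lower (RBPjcKO replicate 2) and 1 lower (wild-type replicate 2), and the mesothelial calls 3 lower (RBPjcKO replicate 3). Neutrophil calls were 8 without wild-type replicate 1 and 1 without wild-type replicate 3 or RBPjcKO replicate 2 or 3, and B cell calls were 1 without wild-type replicate 1 or RBPjcKO replicate 1 or 2. Without wild-type replicate 2, B cell, dendritic and platelet calls were 0, 0 and 1. Gzmb stood at 33.0 ± 7.98 and 16.8 ± 19.7 CPM, Krt8 at 70.8 ± 18.9 and 39.1 ± 12.8 CPM, and the globin genes Hba-a1 and Hba-a2, whose reads cannot be told apart, each near 3 CPM in wild-type cells. Camera called 9 of the 11 marker lists at adjusted p between 2.05e-06 for hepatocytes and 0.0374 for platelets, and gave 0.713 for dendritic and 0.476 for erythroid markers. With an estimated correlation 0 of the 11 were called, at adjusted p = 0.51 for cholangiocytes, B cells and platelets, 0.53 for neutrophils and mesothelial cells, 0.60 for hepatocytes, 0.65 for T and NK cells and for macrophages, and 0.66 for stellate cells, and 0 had an unadjusted p under 0.05.

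**Figure D4:**
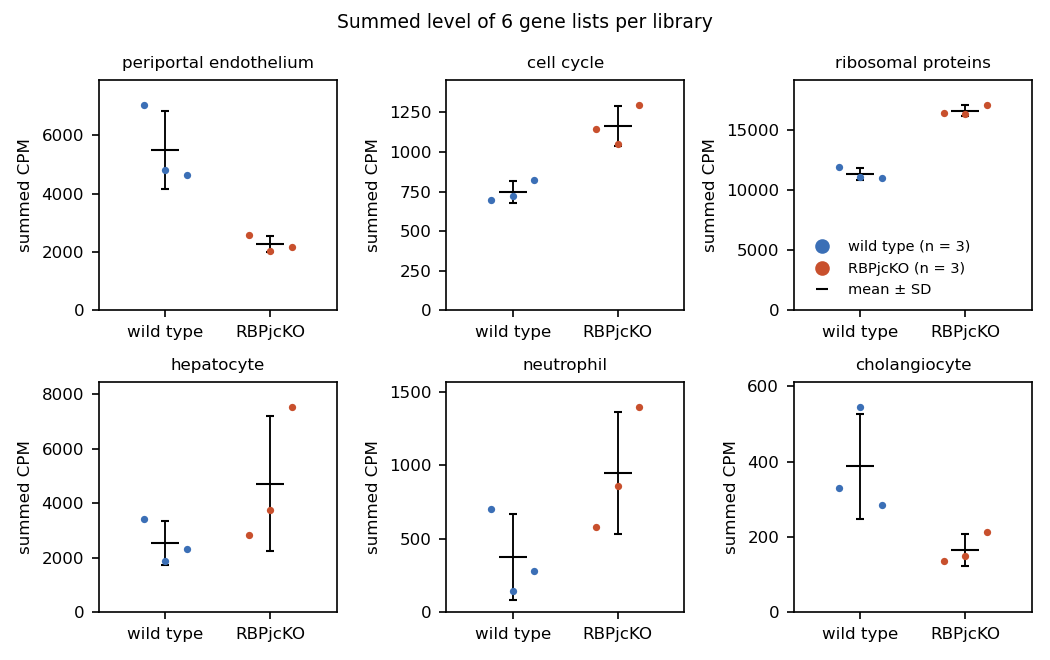
Each point is 1 library (wild type in blue, RBPjcKO in red, n = 3 each), plotted as the summed TMM-normalised CPM of a gene list, with bars for mean ± SD. Ribosomal protein sums are 11360 ± 495 CPM in wild type and 16630 ± 444 CPM in RBPjcKO, hepatocyte sums overlap between the groups, and 1 RBPjcKO library holds 7531 CPM of hepatocyte markers.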

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

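Signal outside the named genes was found in the FANTOM3 cDNA clones, which the comparisons above do not use. Of 33353 clones, 7748 lie apart from every named gene, and 1775 of these had enough counts to be tested, of which 36 were higher and 58 lower in RBPjcKO by edgeR's quasi-likelihood test. The lowest p belonged to a clone on chromosome 7 (117670564 to 117673577, GRCm38), at 1.28 CPM in wild-type and 24.2 CPM in RBPjcKO cells (log2 fold change 4.24, adjusted p = 0.000303). A clone at 75769040 to 75772046 of the same chromosome fell from 60.9 to 20.6 CPM (log2 fold change -1.56, adjusted p = 0.00298). Several clones cover the same locus, so the number of loci is lower than the number of clones. No explanation was tested for them, and unannotated ends of neighbouring genes remain open.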

How the results depend on the processing

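The hepatocyte covariate, clones, scaling, robust, RPKM and CPM filter alternatives were chosen after the data were seen. Leaving out 1 library gave 796 to 1836 called genes against 2489 (467 to 1069 higher, 329 to 824 lower) and 7 to 11 Notch genes against 13, with fewer libraries in each fit. With the hepatocyte covariate the calls were 388 (209 higher, 179 lower) and 6 Notch genes. The covariate takes a degree of freedom and overlaps with genotype, and the cause was not tested further. An adjusted p under 0.01 left 605 (389 higher, 216 lower), and an absolute log2 fold change of at least 1 left 895 (465 higher, 430 lower), both by construction. Under the other settings the count was 2176 to 3632, DESeq2 being the highest, with 2478 of its genes shared. Upper-quartile scaling moved the median of all tested genes to -0.05 and the share called higher from 53.8% to 46.7%.

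Of 20 biology lists, camera called 9 at the preset correlation and 1 with an estimated correlation, and fry called 7. Those 7 include the Notch target and venous lists, which camera did not call. The senescence, inflammation, glycolysis and antigen presentation lists were called by camera but not by fry (adjusted p = 0.0774, 0.0774, 0.0774 and 0.13). Of 11 lists of other cell types camera called 9, against 0 with an estimated correlation (0 at an unadjusted p under 0.05) and 0 by fry (3 at an unadjusted p under 0.05). The estimated correlation allows for genes of a list that vary together, but a lost call does not show by itself that they do. Angiocrine genes had an estimated correlation of 0.02, and their unadjusted camera p still rose from 0.0146 to 0.0869. Periportal genes had an estimated correlation of -0.08, below the preset 0.01, and their unadjusted camera p rose from 8.6e-19 to 0.000707. A higher correlation therefore did not cause that rise. Of 110 called named genes, 110 kept their direction in those of the 16 settings that tested them. Some genes at low levels, such as Mpo and Elane, were not tested in every setting. By DESeq2 110 were called, and 64 were called in each of the 6 fits without a library. Depth limits genes near 0 such as Ism1, Prdm8 and Meox2.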

Other observations

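The loci, neighbouring pairs, families and channel genes here, the progenitor test, the restricted zone test, and the nucleolar and hepatocyte zone lists were chosen after the data were seen. Genes beside the imprinted Peg10 on chromosome 6 were looked up, and imprinted genes as a set were not tested. Besides Peg10 (4747306 to 4760516), Asb4 rose 3.84-fold (13.6 ± 1.41 to 52.3 ± 22.9 CPM), Ppp1r9a 2.21-fold and Sgce 1.29-fold, the last with an adjusted p of up to 0.097 when a library was left out, while Casd1 was not called (30.4 ± 4.33 and 39.6 ± 1.31 CPM). Mest, a second imprinted gene of that chromosome (30733506 to 30748466), rose 9.48-fold from 31 ± 6.07 to 294 ± 140 CPM. Copg2, which overlaps the end of Mest on the other strand, rose 4.23-fold. Reads of the Mest locus may be counted in Copg2, which was not tested. The imprinted growth inhibitor gene Grb10 on chromosome 11 rose 2.13-fold. Inha, which encodes inhibin alpha and lies beside Obsl1 on chromosome 1, rose 6.41-fold from 0.960 ± 0.108 to 6.18 ± 0.735 CPM.

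Genes called in the same direction lay beside one another more often than under permutation of positions. Of 13571 adjacent pairs that do not overlap, both genes were higher in 178 (mean of 10000 permutations 109.8, highest 150) and both lower in 118 (mean 81.17, highest 113), with p = 1e-04 by permutation for each, the smallest these can give. Pairs called in opposite directions numbered 134, below the permuted mean of 189.2. Permuting positions does not keep related genes together, such as Fga, Fgb and Fgg on chromosome 3, so such clusters can contribute. Potassium channel genes were not tested as a set. Of those picked, Kcnj2 rose 5.83-fold (4.22 ± 1.23 to 24.6 ± 2.76 CPM), Kcnj8 2.81-fold and Kcnk5 2.59-fold, and Kcnk3 fell 6.37-fold (3.43 ± 1.05 to 0.536 ± 0.0747 CPM) and Kcnd3 4.71-fold. Of 166 families of related symbols, 7 were called by camera and 0 with an estimated correlation (adjusted p = 0.96), among them Rpl (31 of 47 higher), Rps (20 of 45 higher), the major urinary protein genes Mup (5 of 11 higher, median 1.74), Serpina (5 of 18 higher) and the cadherin genes Cdh (3 of 11 lower, median -0.78).

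Cell cycle genes such as Cenpf, Bub1 and Kif11 were higher in RBPjcKO. Cycling blood progenitors stay open. The largest mean gain among myeloid, erythroid and lymphoid progenitor genes was 3.415 CPM per gene, against 13.94 for the cell cycle genes (SE of the difference 3.261), but no table here gives the profile of such cells, and the 3 myeloid genes (Mpo, Elane and Prtn3) were all called higher, at a median log2 fold change of 4.14 against 2.24. Their sums were 3.68, 7.62 and 21.1 CPM in the RBPjcKO libraries, and 2 were called in each fit without a library except that without RBPjcKO replicate 1, at a median of 2.84 without RBPjcKO replicate 3, and 1 with the hepatocyte covariate, at 2.39. With the hepatocyte level as covariate, for hepatocyte RNA carried into the RBPjcKO libraries, the median of the cell cycle genes was 2 against 2.24 without it, while calls fell from 21 to 2 in a fit with fewer degrees of freedom. Division of the endothelial cells themselves is a hypothesis that was not tested, since these data do not separate them from other cycling cells.

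Ribosomal protein genes such as Rplp0 and Rps2 were higher together with Myc, whose product is known to drive ribosome production. Transcript length was tested because these genes are short, and their median log2 fold change was 0.4854 after a trend with length was removed and 0.5606 before. Under a wider growth programme with Myc, nucleolar and ribosome biogenesis genes should be higher too. They had a median of 0.27, with 8 of 28 called higher (1 without wild-type replicate 2, 2 without RBPjcKO replicate 2 or 3, 3 without wild-type replicate 1) and camera p = 0.0002957, but p = 0.3613 with an estimated correlation. A growth programme that includes Myc is a candidate explanation, and reads shared with pseudogenes were not tested.

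The hepatocyte markers Fgb and Apoa1 rose with 4 others of 34, at sums that overlapped between the groups, and 0 were called without wild-type replicate 2 or 3. If 1 hepatocyte source were present at different amounts, pericentral and periportal hepatocyte genes would rise alike. The pericentral minus periportal mean log2 level was instead higher in RBPjcKO by 0.7982 (SE 0.2012), at -0.52, -0.18 and -0.58 against -1.08, -1.54 and -1.05 in wild-type libraries. Restricted to genes of hepatocytes (13 pericentral, 16 periportal) the difference was 1.204 (SE 0.3347). Summed levels of the full lists did not show this shift. Pericentral sums were 1833 ± 265 and 1806 ± 244 CPM in wild-type and RBPjcKO libraries, and periportal sums 1279 ± 347 and 1595 ± 1025 CPM. Of 21 pericentral genes 2 were called higher, and of 19 periportal genes 1 was called lower. A shift in the zone of the hepatocytes carried along, or in their expression, may contribute, and the 2 were not separated.

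The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The split by genotype gave 2489 called genes (5139 at an unadjusted p under 0.05) and was the 1 split with that many, and the highest of the other splits gave 0 by edgeR (621 as the highest number at an unadjusted p under 0.05, DESeq2 not run on these). Each of the other splits mixes the genotypes, so the difference between them adds to the spread within groups. Their 0 calls therefore do not measure how many calls arise without a difference.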
